A study of Arabidopsis thaliana with 15 samples.

How the data were processed

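Total RNA and small RNA were profiled in leaves of 3-week-old Arabidopsis thaliana plants. Per the labels, total RNA was isolated with Trizol and RNA-seq libraries were made with a stranded total RNA kit, while small RNA libraries followed a separate published protocol. The genotypes were Col-0, the wild-type accession, and prp4k3, which the series' design text describes as a line carrying an artificial microRNA against PRP4K genes. Each genotype had 3 libraries per assay, so 12 libraries were used. The labels also list 3 RNA-seq samples of se-2, which were not analysed here.

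The deposited tables hold read counts per gene, transposable element and At-NC locus for RNA-seq, and read counts per named miRNA for small RNA-seq. Per the submitters' processing notes, the tools were TopHat2, SAMtools, HTSeq and edgeR; their versions, their roles and the genome build are not given in the sources used here, and no coordinates are printed. Beside the counts, the deposited tables give a scaled score per library, rounded to whole numbers, which was checked but not used in any test. The authors' deposited tables also hold a linear fold change (a ratio), a log2 fold change and a p-value with its adjusted value for each feature, per the file headers. Whether the counting used strand is not given, so counts of overlapping and antisense genes are uncertain. Near-identical paralogs may share or lose reads in the same way. In the small RNA table, 54 features with at least 20 reads fell into 22 sets of rows with identical counts in all 6 libraries, so the reads of mature miRNAs with 1 shared sequence appear to be counted more than once.

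The RNA-seq table lists 73194 features, of which 28246 had a count in some library. Library totals were 18305640, 19344157 and 18325566 counts in Col-0 and 16955629, 16041754 and 16532386 counts in prp4k3. The small RNA table lists 427 features, 367 of them with a count. Its totals were 1156591, 792586 and 1083033 counts in Col-0 and 346060, 636914 and 305617 counts in prp4k3, so prp4k3 miRNA values rest on fewer reads. A floor of 3 counts corresponds to between 0.155 and 0.187 CPM (counts scaled by library size) per RNA-seq library and between 2.59 and 9.82 CPM per small RNA library. These floors use total counts without TMM factors, so they are not on the TMM scale of the levels printed below. Intervals and floors cover counting error only, since the reads carry no molecular identifiers that were described.

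Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3: the filterByExpr filter, TMM factors, and the quasi-likelihood F-test of genotype with no replicate block. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. The filter left 18609 RNA-seq features and 215 miRNAs. Values after ± are standard errors for log2 fold changes and standard deviations over 3 libraries for levels, and CPM values are TMM-scaled. Log2 fold changes are prp4k3 against Col-0. Nothing in the labels says that the libraries came from separate plants, so p-values measure only the spread between these samples, which may be technical. In a chi-square comparison of counts every pair of libraries of a group differed by more than sampling noise, so each was kept as 1 replicate.

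Gene lists, named-gene rules and alternatives were fixed before the data were examined. Lists comprised 21 hand-made sets and 6 annotation classes, and the reference table of assembly TAIR10.1 supplied symbols and biotypes only. It matched 28009 of 28496 nuclear genes, and 12 list members were dropped because the listed name was neither the symbol nor a synonym it gives for the locus. Members whose locus has no symbol there were kept. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, and again with an estimated correlation and with fry. A miRNA family was the summed count of its members, tested in the same way as single miRNAs. Named RNA-seq genes were the PRP4K genes and SE, the 6 largest called rises and falls with a symbol, a mean of at least 5 CPM in the higher genotype and all 3 libraries of a genotype on one side, and the 2 members of each list with the lowest adjusted p among those called (6 for miRNA targets). Named miRNAs were the 6 largest called rises and falls with at least 10 CPM, the 5 most abundant features and 13 families. For genes with 1 to 3 counts in a genotype the ratio is given with an exact 95% counting interval. Other features are named only where the text says that they were chosen after their values were seen.

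Alternatives were RLE factors, DESeq2 1.42.0, the edgeR likelihood ratio test, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a 2-fold threshold, a replicate block, removal of organelle and rRNA genes, and each library left out in turn. Upper-quartile factors and total-count scaling were planned for small RNA; total-count scaling of RNA-seq, keeping rows with identical counts once and, for the direction of conserved miRNAs, leaving out miR169 members or counting families were chosen after seeing the data. Correlations used 100000 permutations, and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 handled the remaining steps.

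The tests were checked on simulated counts with the real means, library sizes and dispersions. For the RNA-seq comparison, run on 18296 genes, 15.4% of 65 genes changed 1.5-fold, 63.1% of 65 changed 2-fold and 98.5% of 65 changed 4-fold were recovered, with 10 false calls among 18101 unchanged genes. Few genes were changed there, in alternating directions, so the TMM assumption that most features do not change was met by design. The real comparison called 12253 of 18609 features, so these rates may not carry over to it. For the small RNA comparison, run on 212 features, 6, 9 and 13 of 13 features were recovered at 1.5-fold, 2-fold and 4-fold, with 1 false call among 173. In the gene-list simulation on 18609 genes, 1 list moved 2-fold was found and 0 of 26 random lists were called. Counts were drawn for each gene independently, so it cannot show how often camera calls lists whose members are correlated. In the family simulation on 87 families, 10 of 10 families raised 4-fold were found.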

Results

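The series compared leaf RNA of prp4k3 plants with that of Col-0 in 2 assays, RNA-seq and small RNA-seq, with 3 libraries per genotype in each. Its title concerns PRP4KA, a kinase that acts on SERRATE (SE), a zinc-finger protein of miRNA processing and splicing. The comparison asks which transcripts and which miRNAs differ when PRP4K genes are targeted. RNA-seq totals ranged from 16041754 to 19344157 counts and small RNA totals from 305617 to 1156591 counts.

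The targeted genes were examined first. AT3G25840, listed before the data were examined as PRP4KA, fell by 0.68 ± 0.13 on the log2 scale in edgeR's quasi-likelihood test (adjusted p = 0.00116), from 10.03 ± 0.914 CPM in Col-0 to 6.26 ± 0.231 CPM in prp4k3 (SD, n = 3). Its direction turned under total-count scaling, where the log2 fold change was 0.16 (adjusted p = 0.28), so the fall is relative to the TMM scale. AT1G13350, listed as PRP4KB, did not pass (log2 fold change -0.41 ± 0.18, adjusted p = 0.0646), and it too lay above 0 under total-count scaling (0.43, adjusted p = 0.0413). It passed when prp4k3 replicate 3 was left out (-0.55, adjusted p = 0.0328). AT3G53640, listed as PRP4KC, had 0 counts in every library, below a floor of 0.155 to 0.187 CPM before TMM scaling. SE mRNA rose by 0.34 ± 0.11, from 30.2 ± 3.28 to 38.4 ± 1.62 CPM (adjusted p = 0.0233), and by 1.19 under total-count scaling (adjusted p = 9.1e-06). On the TMM scale that call was lost without Col-0 replicate 1 (adjusted p = 0.0897), prp4k3 replicate 1 (0.0697) or prp4k3 replicate 3 (0.0577).

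Much of the leaf transcriptome differed between the genotypes. Genes of salicylic acid defence and senescence were mostly higher in prp4k3, and photosynthesis genes, MIR genes and TAS loci mostly lower, with the counts and tests given by list below. Of 18609 tested features, 12253 were called, 6310 of them higher and 5943 lower in prp4k3. Called members were thus common in any list, and the list counts below are to be read against that share. With total-count scaling, chosen after seeing the data, the split was 12490 higher and 1825 lower, or 87.2% higher against 51.5%. That scaling moved the median log2 fold change of all features from 0.02 to 0.86. The 10 most abundant features, 7 of them plastid-encoded, held 42.62% of counts in Col-0 and 28.75% in prp4k3. Without them that median was 0.542, and without the 100 most abundant it was 0.294. With organelle and rRNA genes left out, TMM gave 6367 higher and 5740 lower. Changes below are relative to the TMM scale. Under total-count scaling the median turned from negative to positive in the lists of miRNA targets, clock, abscisic acid and cold, flowering time, flavonoid, phosphate starvation and root genes and of PRP4K genes with SE, and most mixed lists had more members higher than lower. All 3 libraries of a genotype lay on one side in 13117 features, or 70.5% of those tested, where chance gives 10%. The authors' deposited table has 6992 features higher and 5946 lower at an adjusted p under 0.05 among 28246.

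The largest rises included stress and immune genes that were nearly silent in Col-0. BIP3, an endoplasmic reticulum chaperone, rose by 9.07 ± 0.51, from 0.0986 ± 0.0854 to 55.3 ± 20.0 CPM (adjusted p = 9.14e-07). FMO1, a monooxygenase of systemic immunity, had 2 counts in Col-0 and 896 in prp4k3, a ratio of 283 with an exact interval of 78.0 to 2340. The ratio was 283 for GLP9, a germin-like protein (78.1 to 2340), and 263 for RLP39, a receptor-like protein (72.6 to 2180). It was 206 for MSRB8, a methionine sulfoxide reductase (70.1 to 999), and 203 for FRK1, a receptor kinase induced by flagellin (56.0 to 1680). The largest falls were in AIF1, which encodes a basic helix-loop-helix protein (-4.87 ± 0.30, 18.7 to 0.631 CPM), and BXL2, a xylosidase (-4.46 ± 0.24, 79.7 to 3.61 CPM). GIS, a zinc-finger gene of trichome formation, fell by 3.61 ± 0.41. RL6, SOFL2 and AGP41 fell by 3.31 ± 0.22, 3.29 ± 0.27 and 3.24 ± 0.23. The adjusted p of these 12 genes was at most 4.5e-05, and each kept its call and direction in all 15 alternatives fitted. Sizes depended on single libraries in some: the log2 fold change was 8.48 for BIP3 without Col-0 replicate 2, 8.45 for MSRB8 without Col-0 replicate 3 (7.55 with all) and -4.36 for GIS without prp4k3 replicate 2. Without Col-0 replicate 3 RLP39, and without Col-0 replicate 2 FRK1, had 0 counts left in Col-0, so their ratios rest on 1 library.

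**Figure D1:**
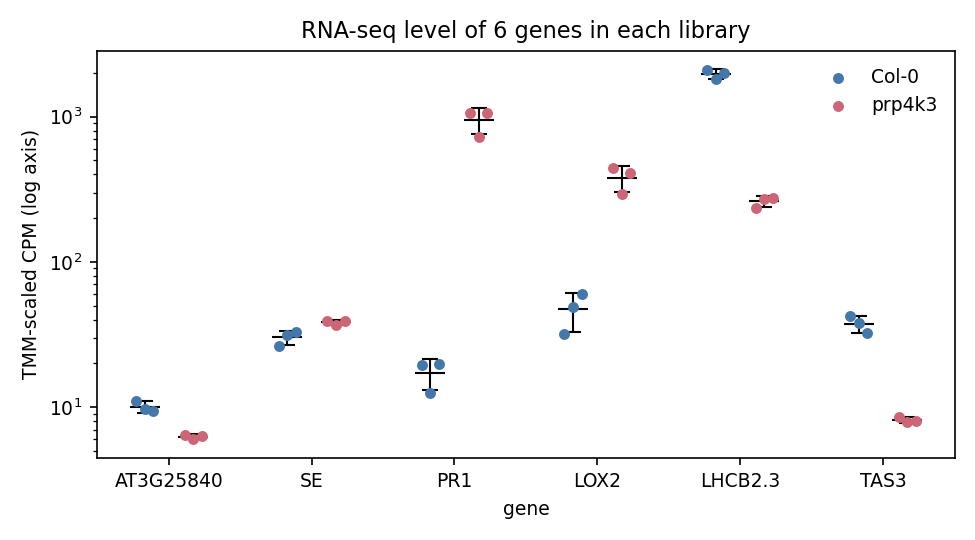
TMM-scaled CPM (log axis) of 6 genes in each RNA-seq library, with points for libraries, horizontal bars for means and error bars for the SD (n = 3). PR1 and LOX2 lie higher in all 3 prp4k3 libraries, and LHCB2.3 and TAS3 lower; AT3G25840 is lower on this scale and not under total-count scaling.

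Salicylic acid defence genes rose together. Of 25 measured members, 24 were higher and 0 lower, with a median log2 fold change of 3.63, and adjusted over the list alone the counts were also 24 and 0. PR1, a marker of systemic acquired resistance, rose by 5.78 ± 0.23, from 17.3 ± 4.09 to 948 ± 190 CPM (adjusted p = 3.44e-07), and FMO1 belongs to the same list. The member not called was WRKY33. In camera the list had an adjusted p of 1.49e-26, and adjusted p = 0.226 with an estimated correlation. Senescence genes moved likewise in 8 of 9 members, with 1 lower (0 under total-count scaling), and adjusted over the list alone the counts were 8 and 1 (median 2.40, camera adjusted p = 0.00463, adjusted p = 0.452 with an estimated correlation). SAG13 rose by 5.25 ± 0.23, from 2.73 to 104 CPM, and NAC6, also called ORE1 and a regulator of leaf senescence, rose by 2.96 ± 0.22.

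Nuclear photosynthesis genes fell. All 31 members were lower, over all genes and adjusted over the list alone, with a median of -1.72, and 30 were also lower under total-count scaling. LHCB2.3, a light-harvesting chlorophyll-binding protein, fell by 2.92 ± 0.11, from 1966 ± 150 to 260 ± 21.5 CPM (adjusted p = 2.9e-07). LHCB4.2 fell by 2.23 ± 0.10, from 1962 ± 127 to 419 ± 28.7 CPM. Near-identical LHCB copies could share reads. The camera adjusted p was 3.51e-26, and adjusted p = 0.226 with an estimated correlation.

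Organelle transcripts made up a smaller part of the prp4k3 libraries. Plastid-encoded genes held 49.1% ± 1.56 of counts in Col-0 and 38.6% ± 0.857 in prp4k3 (SD, n = 3), and mitochondria-encoded genes 0.318% ± 0.00209 and 0.570% ± 0.00587. In each case the 3 values of a genotype lay apart, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. Among 95 tested plastid-encoded genes, 73 were lower and 10 higher (median -0.86), and adjusted over the list alone 75 were lower and 10 higher. The camera adjusted p was 1.99e-11, and adjusted p = 0.326 with an estimated correlation. The most abundant plastid features, ATCG00020 and ATCG00490, were chosen after their values were seen and fell by 1.31 ± 0.07 and 1.67 ± 0.10. Under total-count scaling 31 plastid genes were higher and 30 lower, so the class has no direction there. Of 37 mitochondria-encoded genes, 11 were higher and 9 lower, adjusted over the list alone 11 and 9 (camera adjusted p = 0.862), and under total-count scaling 33 were higher and 1 lower.

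Small RNA pathway genes moved in different directions. In the list of miRNA processing and silencing proteins, 24 of 38 members rose and 2 fell, and adjusted over the list alone the counts were 24 and 2, while under total-count scaling 36 rose and 0 fell (median 0.77, camera adjusted p = 0.00463, adjusted p = 0.326 with an estimated correlation). AGO2, an Argonaute of antiviral silencing, rose by 2.33 ± 0.20, from 3.88 to 19.5 CPM, and EMB2770, listed as the splicing factor STA1, rose by 1.42 ± 0.11. MIR gene transcripts fell in 17 of 18 measured genes, with 0 higher, and adjusted over the list alone the counts were the same 17 and 0 (median -1.30, camera adjusted p = 0.00132, adjusted p = 0.233 with an estimated correlation). MIR414 fell by 1.72 ± 0.16 and MIR157c by 2.46 ± 0.23. With total-count scaling 7 MIR genes were lower and 1 higher. TAS loci, which give rise to trans-acting small RNAs, fell in 4 of 5 members, and in 4 adjusted over the list alone (median -1.03, camera adjusted p = 0.0298, adjusted p = 0.378 with an estimated correlation). TAS3 fell by 2.198 ± 0.13, from 37.5 ± 5.04 to 8.16 ± 0.385 CPM, and TAS1A by 1.03 ± 0.14 (not called under total-count scaling, adjusted p = 0.234). The TAS list lost its call without prp4k3 replicate 2 (adjusted p = 0.0663), and under total-count scaling 1 locus was lower and 1 higher.

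These 7 lists were the ones called by camera among 27. With an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, and fry called 14. Other splits of the 6 libraries gave between 6 and 10 called lists, so the number of lists called by camera does not set the real grouping apart.

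Some stress lists held changed members without passing camera. Among all 18609 tested features 12253 were called, so the number of called members alone does not set these lists apart. In the jasmonate list 14 of 21 members rose and 2 fell, adjusted over the list alone 14 and 2 (adjusted p = 0.106), or 17 and 0 under total-count scaling. LOX2, a lipoxygenase of jasmonate synthesis, rose by 3.01 ± 0.24, from 47.0 to 380 CPM, and VSP1 by 3.76 ± 0.49. That list passed when Col-0 replicate 3 (adjusted p = 0.000822) or prp4k3 replicate 2 (0.049) was left out. In the heat shock list 7 of 11 members rose and 2 fell, adjusted over the list alone 7 and 2, or 8 and 0 under total-count scaling (adjusted p = 0.139, and 0.00389 without prp4k3 replicate 3). HSP90.1 rose by 5.49 ± 0.56 and varied among prp4k3 libraries (56.3 ± 35.4 CPM), with 4.89 without prp4k3 replicate 2, and BIP3 is the other member named. Abscisic acid and cold genes went both ways, with 8 higher and 7 lower of 22, adjusted over the list alone 8 and 7 (adjusted p = 0.837); the median was -0.08 and the mean 0.29, while under total-count scaling the median was 0.76, with 13 higher and 3 lower. HAI1, a phosphatase of abscisic acid signalling, rose by 3.36 ± 0.22. LTI65, listed as RD29B, had 1 count in Col-0 and 212 in prp4k3, a ratio of 134 (23.7 to 5310), and the Col-0 count lay in replicate 1.

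**Figure D2:**
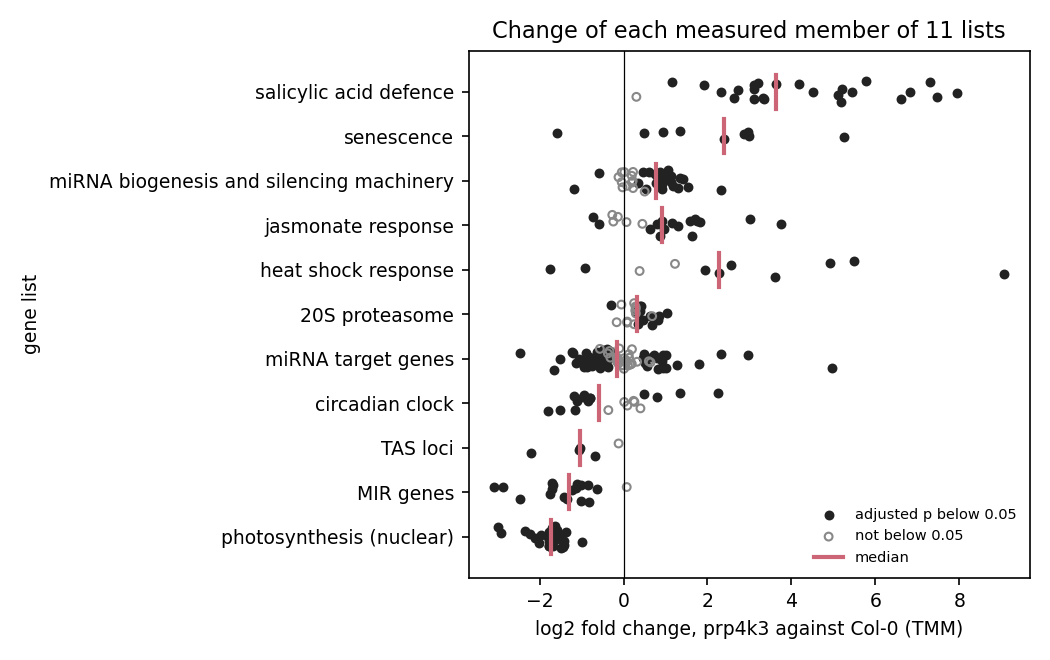
Log2 fold change of each measured member of 11 gene lists on the TMM scale, with filled points at an adjusted p below 0.05, open points otherwise and bars at the medians. The median lies at 3.63 for salicylic acid defence and at -1.72 for photosynthesis; under total-count scaling the medians are 4.47 and -0.88, and those of the miRNA target and clock lists turn to 0.69 and 0.27.

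Lists close to the series' subject were mixed. Core spliceosome members were higher in 10 and lower in 2 of 18, adjusted over the list alone 10 and 2 (camera adjusted p = 0.246), led by AT1G28060, listed as PRP3, at 1.82 ± 0.13, and by EMB2770. Under total-count scaling 17 were higher and 0 lower. SR proteins, which guide splice site choice, were higher in 6 and lower in 6 of 19, adjusted over the list alone 6 and 6 (0.862), while under total-count scaling 17 were higher and 0 lower. RS31 rose by 1.07 ± 0.11 and RS2Z33 fell by 0.77 ± 0.11, with RS2Z33 at 0.08 under total-count scaling. The 20S proteasome, the core protease named in the series' title, was higher in 12 and lower in 1 of 24, adjusted over the list alone 11 and 1 (0.253), and under total-count scaling 24 were higher and 0 lower. Its subunits PAA2 and PAA1 rose by 1.05 ± 0.13 and 0.82 ± 0.11. The list of PRP4K genes and SE had 1 higher and 1 lower of 3, adjusted over the list alone 1 and 2 (0.787), and 2 higher and 0 lower under total-count scaling.

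Targets of miRNAs were lower in 32 and higher in 18 of 76 members, adjusted over the list alone 32 and 18, with a camera adjusted p of 0.5. Under total-count scaling 49 were higher and 4 lower. SPL15, a target of miR156, fell by 2.47 ± 0.24, RAP2.7, listed as TOE1 and a target of miR172, by 1.07 ± 0.12, and the auxin receptor genes TIR1 and AFB3, targets of miR393, by 1.23 ± 0.14 and 0.76 ± 0.10. AGO2 and NAC6 are the risen targets named. RAP2.7 was not called under total-count scaling (adjusted p = 0.125) and AFB3 lay at 0.08 there.

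Growth, timing and metabolism lists had no camera call. Clock genes were lower in 10 and higher in 4 of 20, adjusted over the list alone 10 and 4 (adjusted p = 0.583), while 9 were higher and 1 lower under total-count scaling. TOC1 rose by 1.34 ± 0.12 and ZTL fell by 0.85 ± 0.11 (-0.01 under total-count scaling). Cell division genes were higher in 9 and lower in 4 of 17, adjusted over the list alone 9 and 5 (0.296), or 14 and 0 under total-count scaling, with the replication genes MCM2 and RNR1 at 2.04 ± 0.15 and 1.70 ± 0.13. Flowering time genes were higher in 4 and lower in 4 of 11, adjusted over the list alone 4 and 4 (0.657), or 6 and 2 under total-count scaling. AGL24 fell by 1.44 ± 0.15 and SVP by 1.04 ± 0.12, and SVP was not called under total-count scaling (adjusted p = 0.182). Glucosinolate synthesis was higher in 5 and lower in 3 of 19, adjusted over the list alone 5 and 3 (0.837), or 13 and 1 under total-count scaling, with CYP79B2 at 1.83 ± 0.15 and MYB34 at -2.15 ± 0.20. Flavonoid synthesis was higher in 1 and lower in 5 of 15, adjusted over the list alone 1 and 5 (0.696), but 7 were higher and 1 lower under total-count scaling, with MYB111 at -1.98 ± 0.34 and TT5 at -0.81 ± 0.20 (0.04 under total-count scaling). Phosphate starvation genes were higher in 1 and lower in 3 of 9, adjusted over the list alone 0 and 3 (0.601), but 3 were higher and 1 lower under total-count scaling. SPX1 fell by 2.09 ± 0.38 and SPX2 by 0.91 ± 0.18, the latter not called under total-count scaling (adjusted p = 0.735).

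Markers of other tissues and noncoding RNA classes were also read. Shoot apex and flower markers were measured for 4 of 12 members, with 3 higher and 1 lower, adjusted over the list alone 3 and 1 (0.787), or 3 and 0 under total-count scaling. AP1 had 3 counts in Col-0 and 78 in prp4k3, a ratio of 16.4 (5.41 to 81.2), and its log2 fold change went from 3.90 to 4.75 without Col-0 replicate 2. STM fell by 0.96 ± 0.24, not called under total-count scaling (adjusted p = 0.686). Root markers were measured for 2 of 7, with 0 higher and 1 lower, adjusted over the list alone 0 and 1 (0.657), and SHR lay at -0.61 ± 0.14 on the TMM scale and 0.24 under total-count scaling. Of 40 snoRNA genes 5 were higher and 2 lower, adjusted over the list alone 2 and 2 (0.862), or 29 and 0 under total-count scaling, with U3B at 1.19 ± 0.19 and SNOR30 at -1.07 ± 0.22, the latter not called under total-count scaling (adjusted p = 0.363). Of 9 snRNA genes 2 were higher and 1 lower, adjusted over the list alone 2 and 1 (0.862), or 9 and 0 under total-count scaling, with U2.7 at 0.56 ± 0.11 and U1.5 at 0.42 ± 0.12. Of 126 tested transposable elements 53 were higher and 39 lower, adjusted over the list alone 53 and 39 (0.692), or 78 and 13 under total-count scaling.

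Mature miRNAs changed in both directions relative to each other. On that scale miR163, miR168 and ath-miR2112-5p rose while ath-miR390b-3p, miR822 and ath-miR396b-5p fell. The small RNA counts cover named miRNAs only, so every scaling used compares a miRNA with the others. A change in the total amount of miRNA cannot be read from them. Whether the lower prp4k3 totals reflect sequencing depth alone cannot be told either. Of 215 tested miRNAs, 80 were called, 40 higher and 40 lower in prp4k3. With rows of identical counts kept once, 40 were higher and 30 lower of 187, so the even split depends on reads counted under several names. Nearly identical rows remain in that setting, and 14 of the 40 lower calls are miR169 rows. The largest rises were ath-miR5028 at 3.88 ± 0.65, with 5 counts in Col-0 and 34 in prp4k3, and ath-miR172c and ath-miR172d-3p, rows with identical counts, at 3.85 ± 0.61 (7.91 ± 6.31 to 116 ± 73.9 CPM). They were followed by ath-miR866-3p at 3.11 ± 0.59, ath-miR2112-5p at 3.06 ± 0.36 and ath-miR5637 at 2.198 ± 0.31. The largest falls were ath-miR390b-3p at -2.199 ± 0.24 (189 ± 17.5 to 41.6 ± 8.17 CPM), ath-miR169a-3p at -2.16 ± 0.48, ath-miR171b-5p at -1.68 ± 0.38, ath-miR822-3p at -1.64 ± 0.25, ath-miR822-5p at -1.59 ± 0.27 and ath-miR5654-3p at -1.52 ± 0.36. Few counts lie behind the largest rises: without Col-0 replicate 3 ath-miR5028 was at 5.27 and ath-miR172c at 4.71, and without prp4k3 replicate 2 ath-miR866-3p was at 2.46. Without prp4k3 replicate 1, ath-miR171b-5p (adjusted p = 0.0546) and ath-miR5654-3p (0.0738) were not called.

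Of the 5 most abundant miRNAs, ath-miR396b-5p fell by 1.28 ± 0.20, from 68520 ± 3590 to 28190 ± 2710 CPM (adjusted p = 0.000962). A fall of 0.65 ± 0.22 in ath-miR159b-3p passed (adjusted p = 0.0437) and was called in 4 of 16 alternatives, with an adjusted p of up to 0.261 without prp4k3 replicate 1. The log2 fold changes of ath-miR396a-5p (-0.26 ± 0.23), ath-miR158a-3p (0.03 ± 0.31) and ath-miR159a (-0.25 ± 0.22) did not pass. Without prp4k3 replicate 2, ath-miR396a-5p (-0.39, adjusted p = 0.00739) and ath-miR158a-3p (-0.38, adjusted p = 0.00567) were called lower.

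That library stood apart from the other prp4k3 small RNA libraries. Its counts differed from theirs by a chi-square of 257 and 262 per degree of freedom, against 8.71 between the others. Without it 103 miRNAs were called, 52 higher and 51 lower. The number called lower was 24 without prp4k3 replicate 1 and 25 without Col-0 replicate 1. TMM placed the median of all miRNAs at -0.14, against -0.03 with RLE or upper-quartile factors. In all 3 libraries of a genotype 121 miRNAs lay on one side, or 56.3%, where chance gives 10%. The authors' deposited table has 45 miRNAs higher and 36 lower at an adjusted p under 0.05 among 367.

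The direction of conserved and other miRNAs was compared. In the conserved families 15 of 122 tested miRNAs were higher and 28 lower, against 25 higher and 12 lower of 93 others (odds ratio 0.262, two-sided Fisher's exact p = 0.00675). With rows of identical counts kept once, the odds ratio was 0.201 (Fisher's exact p = 0.00185). Members of a family are not independent: 14 of the 28 lower conserved miRNAs belong to miR169, and without that family the counts were 15 and 14 against 25 and 12 (odds ratio 0.52, Fisher's exact p = 0.214). Without prp4k3 replicate 2 the count over all members did not pass either (odds ratio 0.461, Fisher's exact p = 0.0715, with 26 higher and 35 lower against 26 and 16). With each other library left out the odds ratio lay between 0.0911 and 0.162, with miR169 members still counted as independent. Copper-responsive families had 2 higher and 1 lower of 11, nutrient-responsive families 1 higher and 3 lower of 9, and the DCL4-dependent miR822 had 2 of 2 members lower. The 3 lower nutrient miRNAs, ath-miR395b, ath-miR395c and ath-miR395f, are rows with identical counts. The miR822 members, ath-miR822-5p and ath-miR822-3p, are forms of 1 miRNA, so neither count is of independent miRNAs.

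Summed by family, 36 of 92 were called, 7 of 24 conserved families (2 higher, 5 lower) and 29 of 68 others (18 higher, 11 lower), with an odds ratio of 0.255, close to that over members, which did not pass over these fewer units (two-sided Fisher's exact p = 0.204). The miR163 family rose by 1.94 ± 0.30, from 2311 ± 948 to 8867 ± 1960 CPM (adjusted p = 0.000824), and miR168, which targets AGO1, by 0.73 ± 0.17, from 8598 ± 575 to 14270 ± 1240 CPM (adjusted p = 0.00578). Both kept their calls in all 10 alternatives. The miR162 family, which targets DCL1, fell by 0.59 ± 0.16 (adjusted p = 0.0133), and miR390, which acts on TAS3, fell by 0.56 ± 0.19 (adjusted p = 0.0376). Their calls were kept in 2 and 3 of 10 alternatives, with the highest adjusted p at 0.376 without prp4k3 replicate 1 for miR162 and at 0.283 under total-count scaling for miR390.

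The other named families did not pass. Log2 fold changes were -0.44 ± 0.23 for miR156/miR157, -0.44 ± 0.19 for miR159, -0.27 ± 0.20 for miR167, -0.19 ± 0.37 for miR398 and -0.12 ± 0.20 for miR173. They were 0.57 ± 0.28 for miR165/miR166, 0.40 ± 0.19 for miR319, 0.39 ± 0.19 for miR172 and 0.35 ± 0.18 for miR408. Leaving out prp4k3 replicate 1 gave calls for miR165/miR166 (1.09, adjusted p = 0.0145), miR172 (0.70, 0.0399) and miR408 (0.62, 0.0369). Leaving out prp4k3 replicate 2 gave calls for miR159 (-0.28, adjusted p = 0.0394), miR167 (-0.39, 0.0266), miR319 (0.47, 0.0275) and miR408 (0.48, 0.0147). Leaving out prp4k3 replicate 3 gave calls for miR165/miR166 (1.05, adjusted p = 0.0161), miR172 (0.78, 0.00887) and miR319 (0.67, 0.0311).

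**Figure D3:**
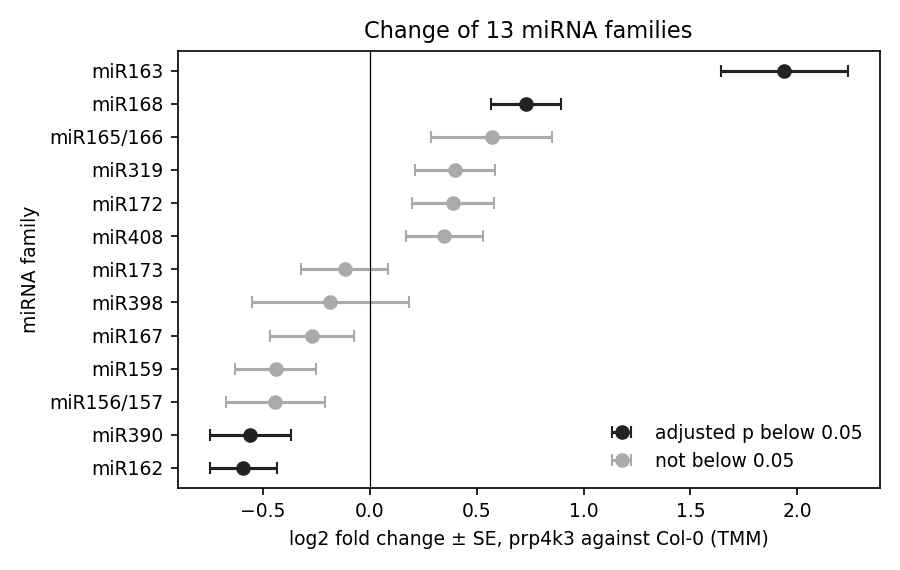
Log2 fold change with its standard error (bars) of 13 named miRNA families on the TMM scale, with black points at an adjusted p below 0.05 and grey points otherwise. The miR163 family lies highest at 1.94 and miR162 lowest at -0.59; miR173, miR167 and miR398 change sign in some alternatives, miR173 also with RLE factors.

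Changes of miRNA families and of their targets were compared across 24 families, which are not independent replicates. Pearson's r between the family log2 fold change and the median of its targets was -0.17 (permutation p = 0.403) and Spearman's rho -0.0983 (permutation p = 0.646), both with an adjusted p of 0.646 over the 2 relations. Without miR827 and miR169, the families farthest from the median, r was 0.0545 and rho 0.0423. Among 13 called targets of called families, 7 moved opposite to their family. DCL1, the target of miR162, rose by 0.83 ± 0.12 (adjusted p = 0.000177), opposite to its family. NLA, the target of miR827, fell by 0.63 ± 0.20 (adjusted p = 0.0177, but 0.21 with adjusted p = 0.34 under total-count scaling) while miR827 rose by 2.17 ± 0.23. AGO1, the target of miR168, lay at -0.04 on the TMM scale and 0.80 under total-count scaling, while miR168 rose by 0.73 ± 0.17. All of these pairs were chosen after their values were seen.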

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

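Total-count scaling of RNA-seq, keeping rows of identical counts once, total-count scaling in the miRNA-target relation and the direction test without miR169 or over families were chosen after seeing the data. Across the counts of changed features, lists and families, the organelle share, the miRNA-target relation and the direction test, 126 of 143 alternative values kept their direction and their side of the threshold or stayed within 1.5 times. With a 2-fold threshold the RNA-seq count was 6301 (3530 higher, 2771 lower) and the small RNA count 52 (25 higher), as fewer features can pass. Total-count scaling gave 12490 higher and 1825 lower RNA-seq features and 25 lower miRNAs. The called lists were 0 with an estimated correlation and 14 with fry, against 7. Mitochondria-encoded genes alone rose by 0.251 percentage points where the summed organelle share fell. With targets of at least 5 CPM Spearman's rho was 0.142; the cause was not tested. The direction test gave an exact p of 0.214 without miR169 members (odds ratio 0.52 against 0.262) and 0.204 over families, where the odds ratio was 0.255 and 36 called families replaced 80 miRNAs. Leaving out 1 library gave 11042 to 12334 RNA-seq features (5733 to 6333 higher, 5309 to 6001 lower), 58 to 103 miRNAs (28 to 52 higher, 24 to 51 lower), 7 to 8 lists, 26 to 46 families and an exact direction p of 3.42e-05 to 0.0715, the last without prp4k3 replicate 2.

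Under total-count scaling the log2 fold changes of AT3G25840 (0.162), AT1G13350 (0.432), AFB3 (0.083), RS2Z33 (0.077), TT5 (0.037) and SHR (0.237) turned, since that scaling moved the median to 0.86. Among miRNAs ath-miR158a-3p turned with limma-voom (-0.062) and the replicate block (-0.056), and miR173 with RLE factors (0.006). With 1 library left out, values that turned in some case ranged from -0.383 to 0.546 for ath-miR158a-3p, -0.386 to 0.094 for ath-miR396a-5p, -0.391 to 0.1 for miR167, -0.38 to 0.217 for miR398 and -0.269 to 0.264 for miR173. The glucosinolate list turned without Col-0 replicate 1 (adjusted p = 0.973), over a range of 0.675 to 0.987. For these the cause was not tested. Named RNAs kept call and direction in 944 of 973 alternative values, named miRNAs in 267 of 288 and named families in 98 of 130.

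As a replicate block, the numbers in the labels gave 11875 RNA-seq features (6122 higher, 5753 lower), 69 miRNAs (30 higher, 39 lower), 9 lists, with jasmonate (adjusted p = 0.029) and heat shock (0.0261) added, and 27 families. Same-numbered libraries correlated at -0.0493, 0.0464 and -0.0468 in RNA-seq and at -0.244, -0.0172 and -0.0767 in small RNA, so the numbers do not pair the samples, and not every sample correlated best with its own number. The se-2 alternatives and the test of intronless genes were not run, as no se-2 column and no exon annotation were used here. Depth limits low miRNA values, since 3 counts equal up to 9.82 CPM before TMM scaling in a prp4k3 small RNA library.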

Other observations

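Chosen only after the results were seen were the grouping of genes by symbol, the tests of scaling, of single libraries and of time of day, the direction tests without miR169, over families and with identical rows kept once, and the splits of the single-gene and single-miRNA tests.

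Genes sharing a symbol prefix were compared outside the fixed lists; a prefix can join unrelated families. Among 111 prefixes with at least 10 tested members, camera called 28. With an estimated correlation it called 0, with 14 at an unadjusted p under 0.05. Genes with the prefix CRK, mostly cysteine-rich receptor kinases with some CDPK-related kinases among them, rose in 27 and fell in 4 of 35 members, with a median log2 fold change of 2.58 and CRK7 at 5.69 ± 0.22. Receptor-like proteins (RLP) rose in 34 and fell in 3 of 44 (median 2.56), with RLP23 at 4.96 ± 0.24. Of 50 WRKY genes, which encode transcription factors and of which 7 are in the fixed lists, 32 rose and 4 fell. ABCC transporters rose in 13 and fell in 1 of 15, with ABCC3 at 4.06 ± 0.13. Calcium-dependent kinases (CPK) rose in 15 and fell in 0 of 20. PDIL genes, which encode disulfide isomerases, rose in 9 and fell in 1 of 12, with PDIL1-2 at 4.61 ± 0.32.

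Fasciclin-like arabinogalactan proteins (FLA) were lower in 12 of 13 members (median -1.49, and -0.65 under total-count scaling). Auxin-induced SAUR genes were lower in 10 of 12 (median -1.98, and -1.14), with SAUR20 at -2.82 ± 0.23. Expansins (EXPA) were lower in 9 of 13 (median -0.82), and their median turned to 0.03 under total-count scaling.

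Salicylic acid defence genes rose and photosynthesis genes fell. Under total-count scaling 55 of the 56 members were called in the same direction. For the photosynthesis genes this argues against scaling to a few abundant genes, since that scaling raised values and 30 of 31 stayed lower. It could only raise the defence genes further, so it cannot decide for them. With organelle and rRNA genes left out, the medians were 3.65 for defence and -1.70 for photosynthesis. A change carried by 1 library is argued against, since 55 of 56 members had all 3 prp4k3 libraries on one side. Sampling at another time of day stays open: of the called clock genes, with phases assigned after their values were seen, 1 morning gene was higher and 7 lower, against 2 evening genes higher and 1 lower (Fisher's exact p = 0.152). An effect of the prp4k3 genotype may account for the pattern but was not separated from growth conditions or infection.

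MIR gene transcripts fell while their mature miRNAs moved both ways, with 1 called higher and 4 lower among 17 pairs. Under total-count scaling 15 of 18 MIR genes lay below 0 (exact binomial p = 0.00754). That test takes the genes as independent, though some share a family and all were measured in the same 6 libraries. Its p therefore does not measure the spread between samples. Only 7 were called lower there, and 1 higher, so scaling to a few abundant genes as the whole cause is argued against for those 7. Mature levels may follow the host transcript in part: Spearman's rho across MIR genes, which are not independent replicates, was 0.636 (permutation p = 0.0076) and Pearson's r 0.626 (permutation p = 0.00825). Without the 2 MIR genes farthest from the median r was 0.461, and without MIR398c, whose mature row equals that of MIR398b, rho was 0.624. Other mature rows are shared too: ath-miR156c-5p has the counts of ath-miR156a-5p, and ath-miR162a-3p nearly those of ath-miR162b-3p. Counts were also nearly equal for ath-miR166a-3p and ath-miR166b-3p, ath-miR167a-5p and ath-miR167b, ath-miR169k and ath-miR169h, and ath-miR172a and ath-miR172b-3p. Such a row may hold reads from several MIR genes, so its pairing with 1 transcript is uncertain. MIR163 goes against mature levels following the transcript. It fell by 0.64 ± 0.18 (0.20 under total-count scaling, not called) while ath-miR163 rose by 1.94 ± 0.31. Altered turnover or processing of the transcripts was not tested.

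Counted by member, conserved miRNAs were more often lower and other miRNAs more often higher in prp4k3 (odds ratio 0.262, Fisher's exact p = 0.00675), and with rows of identical counts kept once the odds ratio was 0.201 (Fisher's exact p = 0.00185). Members of a family are not independent, and 14 of 28 lower conserved miRNAs belong to miR169. Without them the odds ratio was 0.52 (Fisher's exact p = 0.214). Over families it was 0.255, close to that over members, and did not pass (Fisher's exact p = 0.204). Whether the smaller number of units hides a difference there cannot be told. Lower depth of the prp4k3 libraries as a cause of the member count was tested at their mean depth only. Thinning Col-0 to 429530 counts per library in 20 draws left a median odds ratio of 0.201 (0.131 to 0.3). The median Fisher's exact p was 0.00455 (highest 0.0394), but these tests count miR169 members as independent. The thinned depth lies above the 346060 and 305617 counts of prp4k3 replicates 1 and 3. The imbalance was thus not fully matched, and depth stays open for the member count. Without miR169 the median odds ratio was 0.422 (median Fisher's exact p = 0.227), so depth stays open there too. Over the few families the median odds ratio was 0.452. Different abundance of the classes stays open, since the exact stratified p of 0.0278 (odds ratio 0.323) counts miR169 members as independent and was 0.306 without them (odds ratio 0.569). So do prp4k3 replicate 2, without which the member test gave a Fisher's exact p of 0.0715 (odds ratio 0.461), and an effect of genotype. With each other library left out, Fisher's exact p over members lay between 3.42e-05 and 0.000477.

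With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real grouping gave 12253 RNA-seq features, 80 miRNAs and 36 families, each in 1 of 10 splits, with 0 as the highest of the others, which all mix the genotypes. For gene lists it gave 7, and 9 of 10 splits gave as many, with 10 as the highest other.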
